A study of Arabidopsis thaliana with 9 samples.

How the data were processed

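The series measured gene expression by RNA-seq in whole rosettes, without roots, of Arabidopsis thaliana plants aged 23 days. It holds 9 libraries in 3 groups, with 3 biological replicates each of wild-type Col-0, jazQ and jazD. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, each library came from a pool of about 20 plants, wild type and mutants shared trays, RNA integrity scores were 7.0 or more, and 9 libraries shared a lane of an Illumina HiSeq sequencer. The labels name the mutant lines but not the mutated genes. That jazQ carries mutations in JAZ1, JAZ3, JAZ4, JAZ9 and JAZ10, and jazD in these and in JAZ2, JAZ5, JAZ6, JAZ7 and JAZ13, is background knowledge of the lines. The labels mark the accession of the jazD plants as Col-0 with an asterisk that they do not explain.

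The authors deposited a table of expected counts per gene from RSEM 1.2.25 with the TAIR10 genome, per the file headers and the submitters' processing notes. The authors also deposited a table of TPM values per gene for the same libraries, per the file headers. Expected counts are estimates that divide reads among the genes they match. Of the values above 0 in a library, 69.11 to 72.61% were whole numbers. Both tables list 33323 nuclear genes, of which 25353 had a count in at least 1 library. The aligner, the trimming, the strandedness of the libraries and the version of the annotation are not given in the sources used here. Gene names came from the tables and from a reference gene table of the assembly TAIR10.1, which matched 32835 of the identifiers. That table was used only for names. Genes were ordered along chromosomes by their identifiers, and copy sequences came from the exons of the reference genome. No coordinates are given because the name of the reference assembly differs from the one of the files.

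Total counts per library ran from 15370271 to 20730459. A total of 3 counts over the libraries of a group was taken as the limit that a count of 0 allows, and a fold against a group at 0 is given as a lower bound against that limit. For groups with 1 to 3 counts the ratio is given with a 95% interval. It comes from the exact Poisson limits of that low count, with the count of the other group taken as known. Reads carry no molecular identifiers, so these limits and intervals cover only the counting error of the lower group.

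Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr on the groups (minimum count 10), which left 19405 genes. Libraries were scaled with TMM, and CPM values, counts divided by scaled library size, are on that scale. A quasi-likelihood F test with robust estimation of the spread was fitted to all 9 libraries together, and each of the 3 comparisons was a contrast of that fit. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with the standard error that the F statistic implies, and CPM as mean with standard deviation, n = 3 libraries per group. The common biological coefficient of variation was 9.03%. The first principal component of the log CPM values held 64.12% of the variance and the second 9.61%.

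A set of 27 gene lists with 369 identifiers was written down from general knowledge of jasmonate action, defence, photosynthesis, growth, other cell types and handling. The name in the files matched for 358 identifiers, 7 had no name there, and 4 with another name were left out. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. P-values were adjusted over the 26 lists with tested members in a comparison. For each list the members called over all genes tested are counted, and beside them the members that pass when p is adjusted over the list alone.

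The genes named were set by rule. They are all 13 JAZ genes. From each other list they are the members with the smallest p, 2 for jazD against Col-0 and 1 for the other comparisons. From each comparison they are also the 5 genes with the largest rise and the 5 with the largest fall among those called, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. Any other gene named is said to have been chosen after its values were seen. The test, the lists, this rule and 10 alternatives to the processing, besides the 9 fits that leave out 1 library each, were chosen before the data were examined. The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom on unrounded counts, other filters on low counts, fits of only the groups compared, the replicate number as a block, and limma on log2 TPM with a pseudocount of 1 or 0.1. TPM values were used without further scaling between libraries. A further 2 alternatives were added after seeing the data.

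The overlap of calls between the mutants was set beside the overlap of independent lists and beside 20 simulations of unchanged groups against the same controls, in which all 9 libraries were drawn from the Col-0 means. The gene test and the list test were first tried on simulated data with known changes. Each simulation of the gene test changed 67, 67 and 66 genes by log2 0.5, 1 and 2 together. This is a far smaller share than the 25.8% of genes called between jazD and Col-0. With a simulated log2 change of 1, jazD against Col-0 gave back 88.1% of 67 changed genes. Over all 3 sizes it had 11 false calls among 162, with 19343 genes tested. The share was 80.6% for jazQ against Col-0, with 13 false calls among 171 over all sizes and 19333 genes tested. It was 82.1% for jazD against jazQ, with 11 among 163 over all sizes and 19319 genes tested. At a log2 change of 0.5 these shares were 43.3, 61.2 and 53.7%. With 1 list shifted in the simulation of jazD against Col-0, camera called that list and 0 others. Simulated genes were drawn independently, so this does not test false list calls where the genes of a list vary together. Correlations estimated for the real lists reached 0.66 (salicylate defence) against the preset 0.01. No columns were left out. Groups of 3 libraries are too small for a test of outlying libraries, and no library was removed.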

Results

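Whole rosettes of Arabidopsis thaliana were profiled by RNA-seq in 3 genotypes with 3 libraries each: wild-type Col-0 and the mutant lines jazQ and jazD. JAZ proteins are repressors that bind jasmonate-responsive transcription factors and are degraded when the hormone jasmonate is perceived. The lines carry mutations in 5 (jazQ) and 10 (jazD) of the 13 JAZ genes, and the comparisons ask which genes differ in expression when these repressors are lost. The plants were 23 days old, and each library held a pool of about 20 rosettes grown with 16 h of light and 8 h of dark at 20 °C. Total counts were 17281630, 16174195 and 18488767 in Col-0 replicates 1 to 3, 15370271, 16377728 and 20730459 in jazQ, and 18914928, 17593005 and 17887924 in jazD. Genes with a count numbered 22200 to 22568 per library. LHCB1.3 or RBCS1A, a light-harvesting protein and a Rubisco subunit, was the most abundant transcript in each library, and the 10 most abundant genes held 8.01 to 9.41% of the counts. Changes are log2 fold changes ± standard error, and levels are counts scaled to library size (CPM) ± standard deviation, with n = 3 libraries per group throughout.

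Transcripts of several mutated JAZ genes were low in the lines that carry the mutation. JAZ1 (AT1G19180), mutated in both lines, had 25.2 ± 1.37 CPM in Col-0, 2.66 ± 0.128 in jazQ and 2.33 ± 0.325 in jazD, and so 10.6% and 9.25% of the Col-0 level. JAZ2 (AT1G74950) and JAZ6 (AT1G72450), mutated in jazD alone, fell there to 13.4% and 20.4% of Col-0 (log2 -2.90 ± 0.23 and -2.29 ± 0.18) and did not pass the test in jazQ (0.64 ± 0.18 and -0.07 ± 0.16). JAZ7 (AT2G34600) had 3 counts in the jazD libraries together against 67 in Col-0, a ratio of 22.6 (95% interval 7.74 to 109.6) that did not pass the test (adjusted p = 0.0937, edgeR), and 209 in jazQ. This fall did pass with the Wald test, with only the groups compared and with the replicate number as a block. It also passed on TPM with either pseudocount, and without jazQ replicate 2 or 3 (fitted values -4.345 and -4.34). Other mutated JAZ genes kept or gained transcript. JAZ3 (AT3G17860) rose in both lines (1.96 ± 0.11 in jazQ and 1.15 ± 0.11 in jazD). JAZ9 (AT1G70700) rose in jazD (1.15 ± 0.23) and did not pass in jazQ (0.28 ± 0.23). JAZ10 (AT5G13220) rose in both (2.48 ± 0.35 and 3.69 ± 0.33), and JAZ13 (AT3G22275) rose in jazD (5.54 ± 0.33, from 0.413 to 19.7 CPM). JAZ4 (AT1G48500) was too low to test, with 0.556, 0.207 and 0.167 CPM in Col-0, jazQ and jazD. JAZ5 (AT1G17380) did not pass (1.77 ± 0.61 in jazQ, or 0.88 without jazQ replicate 2, and 0.71 ± 0.66 in jazD), although its jazD value passed with only the groups compared and without jazQ replicate 2 (0.72). JAZ7 and JAZ13 did not pass in jazQ (1.66 ± 0.76 and 1.39 ± 0.52), although JAZ7 passed there with the replicate number as a block (1.52). An insertion can leave transcript on either side of it, so a level above 0 in a mutated gene checks nothing.

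Of the JAZ genes mutated in neither line, JAZ8 (AT1G30135) rose in jazD (4.15 ± 0.96, from 0.422 to 7.57 CPM) and JAZ12 (AT5G20900) rose in jazD by a small amount (0.32 ± 0.06), while JAZ11 (AT3G43440) did not pass (0.05 ± 0.13). In jazQ these 3 genes did not pass, with values of 3.14 ± 1.06, 0.21 ± 0.06 and 0.01 ± 0.13, while JAZ2 and JAZ8 did pass there with the Wald test. Replicate 2 of jazQ stood apart from the other jazQ libraries in several of these genes, with 18.3 CPM of JAZ5 against 5.52 and 4.72 and 8.50 CPM of JAZ7 against 2.46 and 1.35. It also had 8.50 CPM of JAZ8 against 1.66 and 1.204, and 26.5 CPM of JAZ10 against 17.0 and 11.7. For JAZ13 it had 2.07 CPM against 0.466 and 0.771. As a list, the JAZ family was not called in jazD against Col-0, where 6 of 12 tested members rose and 3 fell (6 and 4 adjusted over the list alone, camera, adjusted p = 0.464). The falls, in JAZ1, JAZ2 and JAZ6, and the rises of JAZ3, JAZ9, JAZ10 and JAZ13 were in genes mutated in jazD. The JAZ genes called in jazQ, JAZ1, JAZ3 and JAZ10, are mutated there. The list thus does not separate effects of the mutations on their own genes from changes of the family. The rise of JAZ8 in jazD lost its call without Col-0 replicate 1, 2 or 3 or jazD replicate 2 (3.79, 4.61, 4.16 and 3.95). The rise of JAZ10 in jazQ lost its call with only the groups compared (2.48) and without Col-0 replicate 1, 2 or 3 or jazQ replicate 1 (2.501, 2.43, 2.499 and 2.52).

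**Figure D1:**
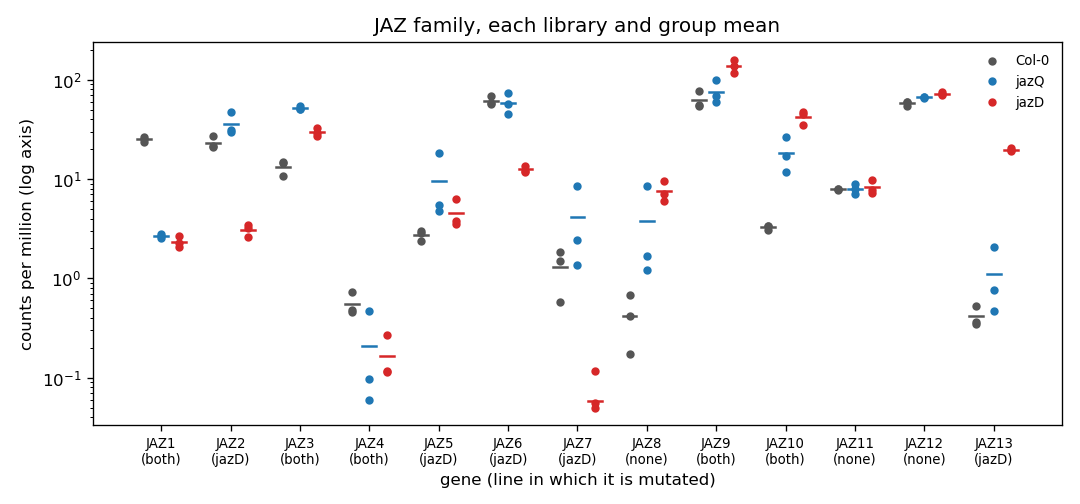
Expression of the 13 JAZ genes in each library, in CPM on a log axis, with points for libraries (3 per group) and bars for group means, and the labels under the genes give the lines in which each is mutated. Values under 0.05 CPM are drawn at 0.05; JAZ1, JAZ2 and JAZ6 lie at 2.33, 3.10 and 12.5 CPM in jazD against 25.2, 23.2 and 61.3 in Col-0, and JAZ13 at 19.7 against 0.413.

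In jazD rosettes, transcripts for jasmonate synthesis and for defence proteins were far higher than in Col-0, and transcripts for cell wall loosening were lower. LOX2 (AT3G45140), a chloroplast lipoxygenase at the start of jasmonate synthesis, went from 532 ± 81.7 to 4862 ± 95.01 CPM (3.19 ± 0.10). The plant defensin PDF1.3 (AT2G26010) went from 10.3 ± 6.94 to 3836 ± 306 CPM (8.52 ± 0.53), and MBP1 (AT1G52040), a myrosinase-binding protein, from 27.2 ± 12.8 to 1402 ± 66.8 CPM (5.68 ± 0.33). The expansin EXPA11 (AT1G20190) fell from 69.2 ± 3.05 to 13.98 ± 0.788 CPM (-2.31 ± 0.09). Of 19405 genes tested, 2580 were higher and 2426 lower in jazD (25.8% of genes), with at least a 2-fold difference in 789 and 385 of them.

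The jasmonate pathway rose at several steps. Of 14 tested genes for jasmonate synthesis, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.33, camera, adjusted p = 8.11e-10), among them LOX2 and the allene oxide cyclase gene AOC2 (AT3G25770) (2.81 ± 0.12). The list for jasmonate breakdown had 6 of 8 members higher and 0 lower (6 and 0 adjusted over the list alone, median 2.55, camera, adjusted p = 3.46e-07), with the jasmonate oxidase gene JOX4 (AT2G38240) at 2.79 ± 0.20 and IAR3 (AT1G51760), an amidohydrolase that cleaves jasmonate and auxin conjugates, at 1.57 ± 0.10. Of 10 signalling genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.36, camera, adjusted p = 0.00158). The members with the smallest p were NINJA (AT4G28910), which links JAZ proteins to a co-repressor (0.52 ± 0.07), and JAM2 (AT1G01260), a repressor that competes with MYC factors (0.79 ± 0.12).

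Both branches of jasmonate defence were higher. All 11 tested members of the ethylene-jasmonate branch (ERF branch) rose, also when adjusted over the list alone (11 of 11, median 4.56, camera, adjusted p = 1.88e-15). The basic chitinase HCHIB (AT3G12500) rose by 3.96 ± 0.11, the thionin THI2.1 (AT1G72260) by 5.91 ± 0.17 and the defensin PDF1.2C (AT5G44430) by 7.71 ± 0.59. The fold changes of PDF1.3 and PDF1.2C became 9.198 and 8.67 without Col-0 replicate 3. The defensin genes are near-identical copies, so how reads were divided among them is uncertain. In the wound and herbivore branch (MYC branch), 9 of 10 members rose and 0 fell (10 and 0 adjusted over the list alone, median 3.604, camera, adjusted p = 1.08e-12), with the arginase ARGAH2 (AT4G08870) at 3.00 ± 0.12 beside MBP1. In the list for ER bodies, compartments that store β-glucosidases, 9 of 9 members rose (9 adjusted over the list alone, median 2.84, camera, adjusted p = 9.33e-16). Its β-glucosidase PYK10 (AT3G09260) changed by 2.76 ± 0.07 and NAI2 (AT3G15950), needed for ER body formation, by 2.85 ± 0.09.

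Genes for tryptophan and for the indole glucosinolates made from it rose together. All 7 tryptophan genes were higher (7 adjusted over the list alone, median 1.63, camera, adjusted p = 1.28e-12), including the anthranilate transferase PAT1 (AT5G17990) (2.01 ± 0.06) and the tryptophan synthase subunit TSB1 (AT5G54810) (2.26 ± 0.08). Of 19 indole glucosinolate genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.34, camera, adjusted p = 1.77e-13), with CYP79B3 (AT2G22330), which converts tryptophan to its oxime, at 2.42 ± 0.08 and the glutathione transferase GSTF10 (AT2G30870) at 1.96 ± 0.08. Aliphatic glucosinolate genes were not called as a list (4 higher and 3 lower of 18, 5 and 3 adjusted over the list alone, median -0.08, camera, adjusted p = 0.98). Their members with the smallest p, the chain-elongation genes MAM1 (AT5G23010) and BCAT4 (AT3G19710), rose slightly (0.31 ± 0.06 and 0.296 ± 0.07), and BCAT4 lost its call on TPM (0.22). Of 11 sulfate assimilation genes, 7 rose and 0 fell (7 and 1 adjusted over the list alone, median 0.71, camera, adjusted p = 5.80e-05), with the reductases APR3 (AT4G21990) at 1.53 ± 0.09 and SIR (AT5G04590) at 0.705 ± 0.06. This call was lost at adjusted p = 0.0559 with an estimated correlation. Of 16 anthocyanin and flavonoid genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 1.83, camera, adjusted p = 1.28e-12), with the anthocyanidin synthase LDOX (AT4G22880) at 2.64 ± 0.10 and the glycosyltransferase UGT79B1 (AT5G54060) at 2.92 ± 0.13.

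Among growth lists, cell wall loosening had 12 of 23 members lower and 0 higher (14 and 1 adjusted over the list alone, median -0.76, camera, adjusted p = 3.77e-07), with EXPA11 and the xyloglucan-modifying enzyme XTH7 (AT4G37800) (-1.13 ± 0.08). Auxin response had 13 of 20 lower and 2 higher (13 and 2 adjusted over the list alone, median -0.698, camera, adjusted p = 6.06e-04). The repressor IAA3 (AT1G04240) fell (-1.34 ± 0.11) and the conjugating enzyme GH3.3 (AT2G23170) rose (1.49 ± 0.10). The auxin call was lost among genes with a mean of at least 5 CPM, where the median was -0.15. Light harvesting and photosystems (13 of 40 lower, 0 higher, 23 and 0 adjusted over the list alone, median -0.17, camera, adjusted p = 3.66e-07) and the Calvin cycle (9 of 15 lower, 0 higher, 11 and 0 adjusted over the list alone, median -0.22, camera, adjusted p = 1.16e-04) were called with small changes. Both calls were lost with an estimated correlation, at adjusted p = 0.399 and adjusted p = 0.273. The antenna protein genes LHCB4.3 (AT2G40100) and LHCB1.4 (AT2G34430) fell (-0.94 ± 0.11 and -0.44 ± 0.10), and so did Rubisco activase RCA (AT2G39730) (-0.497 ± 0.07) and phosphoribulokinase PRK (AT1G32060) (-0.39 ± 0.06). LHCB1.4 has near-identical copies, and its value is uncertain for that reason. Leaf senescence had 8 of 9 members higher and 0 lower (8 and 0 adjusted over the list alone, median 1.09, camera, adjusted p = 3.46e-05), with the factor NAP (AT1G69490) at 1.51 ± 0.12 and the protease SAG12 (AT5G45890) at 5.26 ± 0.54, or 6.02 without Col-0 replicate 1. Among genes with a mean of at least 5 CPM the median for senescence was 0.44 and that of the ERF branch 5.91. Of the lists called in jazD against Col-0, only sulfate assimilation, light harvesting and the Calvin cycle lost their calls with an estimated correlation. The others held with it at adjusted p from 0.0212 to 0.0433 (camera).

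The remaining lists were not called in jazD against Col-0 (camera). The adjusted p was 0.464 for salicylate defence (2 higher and 3 lower of 15), 0.514 for cell cycle and DNA replication (0 and 1 of 28), 0.795 for the gibberellin pathway (3 and 3 of 13) and 0.862 for the circadian clock (0 and 1 of 10). It was 0.655 for heat shock (1 and 0 of 4), 0.129 for touch and handling (2 and 0 of 5), 0.243 for flowering (0 and 1 of 3), 0.285 for trichome markers (1 and 0 of 5) and 0.514 for guard cell markers (1 and 0 of 5). Adjusted over the list alone the higher and lower counts were 2 and 3, 0 and 0, 3 and 3, 0 and 0, 1 and 0, 3 and 0, 0 and 1, 0 and 0, and 1 and 1, in that order. The gibberellin list had a median of -0.017, a mean of 0.030 and a test direction of down. None of the 6 root cell markers had enough counts to be tested. The gibberellin-regulated gene GASA6 (AT1G74670) fell (-2.08 ± 0.08), the DELLA gene RGL3 (AT5G17490) rose (2.77 ± 0.28), and the flowering regulator SOC1 (AT2G45660) fell (-0.36 ± 0.07). FAMA (AT3G24140), a guard cell factor, and WRKY33 (AT2G38470) rose (0.39 ± 0.10 and 0.95 ± 0.19), and FAMA lost its call on TPM (0.303). Some calls were lost under several alternatives. The calls of EDS5 (AT4G39030) (0.64 ± 0.17), ALD1 (AT2G13810) (-0.95 ± 0.24), TSO2 (AT3G27060) (-0.19 ± 0.06), HSP70-4 (AT3G12580) (0.65 ± 0.17), WRKY40 (AT1G80840) (1.21 ± 0.33), PRR9 (AT2G46790) (-0.61 ± 0.17) and GL2 (AT1G79840) (0.305 ± 0.10) were each lost without jazD replicate 1, at 0.61, -1.01, -0.17, 0.61, 1.23, -0.65 and 0.21, and for each also without other single libraries. The call of TSO2 was also lost with the Wald test, those of TSO2, WRKY40 and PRR9 without a filter, and that of GL2 with the Wald test, with limma-voom, with only the groups compared and on TPM. Not called were CYCD3;1 (AT4G34160) (0.26 ± 0.09), TOC1 (AT5G61380) (0.53 ± 0.20), FUL (AT5G60910) (-0.47 ± 0.21), MYB60 (AT1G08810) (-0.25 ± 0.09), HSP18.2 (AT5G59720) (0.48 ± 0.19) and MYB23 (AT5G40330) (0.35 ± 0.17). Of these, CYCD3;1 passed with DESeq2 size factors, at a mean of at least 5 CPM and with only the groups compared. It also passed with the replicate number as a block and without jazQ replicate 2 or 3. TOC1 passed with the Wald test, with limma-voom and with the replicate number as a block. It also passed without Col-0 replicate 3 or jazD replicate 1 (0.71 and 0.68). MYB60 passed on TPM and FUL on TPM with the larger pseudocount.

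Most of the genes with the largest differences between jazD and Col-0 had counts at or near 0 in 1 of the groups. Apart from the defensins, the largest rises were in AT5G28800 (0 counts in Col-0, at least 206-fold higher in jazD), AT5G47260 (0 counts in Col-0, at least 206-fold higher) and AT5G28810 (9.89 ± 0.21, from 0.0760 to 78.9 CPM). The largest falls were in AT5G50565 (0 counts in jazD, at least 248-fold lower), AT5G49440 (-9.71 ± 0.20), AT5G49640 (1 count in jazD against 776, a ratio of 786 with a 95% interval of 141 to 31028), AT5G55790 (2 counts against 799, a ratio of 404 with an interval of 112 to 3339) and AT5G45490 (-4.31 ± 0.10). These 8 genes all lie on chromosome 5. In the order of genes, 863 tested genes stand from AT5G44490 to AT5G55790. These ends are the first and last of 10 genes nearly silent in jazD and expressed in Col-0 and jazQ, found in these data. Nearly silent means a mean under 0.3 CPM and expressed a mean above 2 CPM. Both words describe counts, and whether transcript was absent was not tested. The 10 had to be called to be chosen, and 36.81% of the other 853 genes were called between jazD and Col-0. With the 10 the share was 37.54%, against 25.25% of the genes outside the stretch. For jazQ against Col-0 these shares were 1.16 and 1.28%. Of the 16 genes expressed in jazD and nearly silent in Col-0 and jazQ, 4 lie on chromosome 5 and only AT5G47260 in the stretch. AT5G28800 and AT5G28810 thus lie outside it. TSB1, UGT79B1 and SAG12, named above, also lie in this stretch, and PDF1.2C (AT5G44430) lies just before it, in the window from AT5G43580. Outside this stretch, 2451 genes were higher and 2231 lower in jazD by the same fit and adjustment. This alternative, chosen after seeing the data, only leaves out the calls of the stretch, so it does not test the other calls. That alternative leaves in the genes next to the stretch.

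Calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On the deposited TPM values the balance of calls differed, with 1869 higher and 3369 lower (35.68% of calls higher, against 51.54% on counts). The counts were 1850 and 3368 with the smaller pseudocount and 1998 and 3150 without a filter. TPM values were not scaled between libraries. The median log2 fold change of all genes tested was -0.0693 on TPM (pseudocount 1) and -0.0026 on counts, so TPM values as a whole lay lower in jazD.

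**Figure D2:**
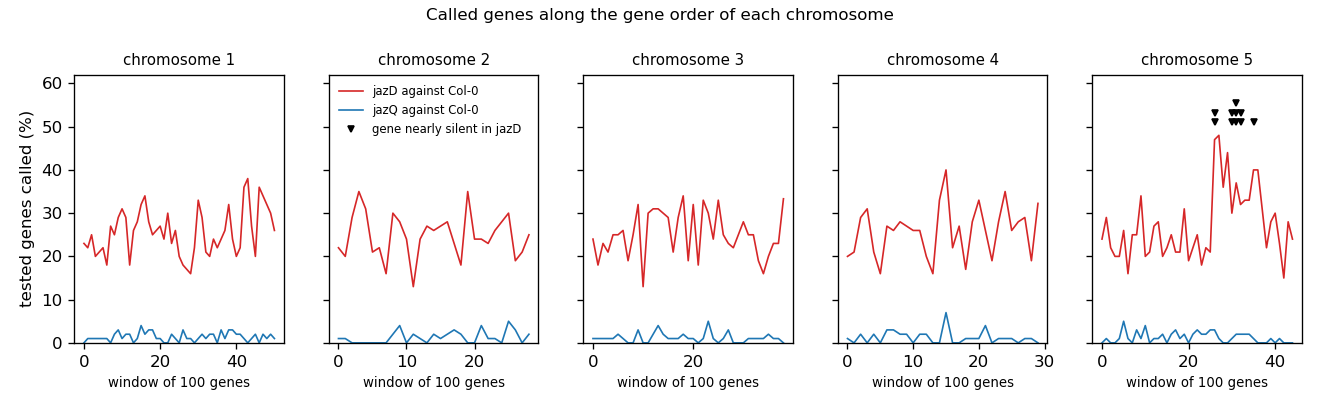
Percentage of tested genes called in consecutive windows of 100 tested genes along each chromosome (the last window of a chromosome can be shorter), for jazD against Col-0 (red) and jazQ against Col-0 (blue); triangles mark the windows of the 10 genes under 0.3 CPM in jazD and above 2 CPM in Col-0 and jazQ, and their height has no meaning. The first and last of the 10, AT5G44490 and AT5G55790, set the ends of the stretch, where 37.54% of genes were called in jazD and 1.16% in jazQ. Without the 10 the share in jazD was 36.81%.

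In jazQ rosettes far fewer genes differed from Col-0. The lists with the smallest p in camera at the preset correlation were aliphatic glucosinolate and anthocyanin genes, which rose, and the ethylene-jasmonate branch. That branch fell as a list although only 2 of its 11 members were called. MAM1, which elongates the side chains of aliphatic glucosinolates, went from 231 ± 7.13 to 419 ± 20.5 CPM (0.86 ± 0.06), and UGT79B1 of the anthocyanin pathway from 2.005 ± 0.141 to 6.48 ± 0.735 CPM (1.68 ± 0.14). The chitinase HCHIB fell from 4.16 to 1.88 CPM (-1.15 ± 0.16). Of 19405 genes tested, 167 were higher and 80 lower in jazQ (1.27%), with at least a 2-fold difference in 51 and 22.

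Of 18 aliphatic glucosinolate genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.63, camera, adjusted p = 9.53e-28). Of 16 anthocyanin and flavonoid genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.02, camera, adjusted p = 1.69e-21). In the ERF branch 2 of 11 members, HCHIB and HEL (AT3G04720) (a PR4 protein, 64.4 and 32.1 CPM, chosen after its values were seen), fell and 0 rose (8 and 0 adjusted over the list alone, median -1.14, camera, adjusted p = 4.05e-13). Its median was -2.06 in a fit of only jazQ and Col-0. PDF1.3 and PDF1.2C had 10.3 and 9.74 CPM in Col-0 and 1.28 and 0.795 in jazQ, and did not pass (-2.96 ± 0.67 and -3.62 ± 0.85). Jasmonate breakdown (2 of 8 higher, 0 lower, 5 and 0 adjusted over the list alone, median 1.24, camera, adjusted p = 5.20e-09) included JOX4 (1.95 ± 0.21). Its median was 0.74 without jazQ replicate 2, which stood apart in several JAZ genes, and 0.73 on TPM without a filter, with the call kept. The ER body list was called upward (2 of 9 higher, 0 lower, 6 and 0 adjusted over the list alone, median 0.37, camera, adjusted p = 5.03e-07). Its β-glucosidase BGLU22 (AT1G66280) had 0 counts in Col-0 and 16 in jazQ, at least 5.33-fold higher, and the list's median is unchanged with this gene at its bound. The call of BGLU22 was lost on TPM without a filter and without Col-0 replicate 1, Col-0 replicate 2 or jazQ replicate 2 (fitted values 5.46, 5.47 and 5.197).

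Auxin response was called downward (2 of 20 lower, 1 higher, 7 and 1 adjusted over the list alone, median -0.32, camera, adjusted p = 6.17e-05), although its member with the smallest p, IAA17 (AT1G04250), rose (0.46 ± 0.07). Cell cycle and DNA replication was called upward with a small median of 0.12 (camera, adjusted p = 4.17e-05), and 0 of its 28 members were called singly, also when adjusted over the list alone. Its member MCM3 (AT5G46280) had 0.26 ± 0.07. These 7 calls held with an estimated correlation, each at adjusted p = 0.034 (camera), so that setting does not rank them. Another 9 calls were lost with it. In camera, the upward ones were the JAZ family (2 higher, 1 lower of 12, adjusted p = 0.142 with an estimated correlation), jasmonate biosynthesis (1 and 0 of 14, adjusted p = 0.0842) and the MYC branch (1 and 0 of 10, adjusted p = 0.175). Further upward ones in camera were sulfate assimilation (0 and 0 of 11, adjusted p = 0.298 with an estimated correlation), the Calvin cycle (0 and 0 of 15, adjusted p = 0.434), trichome markers (1 and 0 of 5, adjusted p = 0.14) and guard cell markers (1 and 0 of 5, adjusted p = 0.298). The downward ones in camera were salicylate defence (0 and 0 of 15, adjusted p = 0.305) and leaf senescence (0 and 0 of 9, adjusted p = 0.115). Adjusted over the list alone the higher and lower counts of these 9 lists were 7 and 1, 6 and 0, 4 and 0, 5 and 1, 0 and 0, 1 and 0, 1 and 0, 0 and 0, and 0 and 0. Sulfate assimilation also lost its call without Col-0 replicate 3, jazQ replicate 1 or jazD replicate 2 (medians 0.077, 0.099 and 0.082), and the Calvin cycle and leaf senescence without jazQ replicate 1 (0.006 and -0.264). Sulfate assimilation and leaf senescence lost theirs also with only the groups compared, and leaf senescence and trichome markers also at a mean of at least 5 CPM. Trichome markers lost theirs without Col-0 replicate 3 or jazQ replicate 3 (0.335 and 0.444), and guard cell markers without jazQ replicate 2 (0.149). The allene oxide synthase gene AOS (AT5G42650) rose (0.74 ± 0.11, with the call lost on TPM without a filter), as did ARGAH2 (1.297 ± 0.11), while APK2 (AT4G39940) (0.54 ± 0.13), RBCS1A (AT1G67090) (0.22 ± 0.08), SARD1 (AT1G73805) (-0.603 ± 0.17) and NAP (-0.43 ± 0.14) did not pass. APK2 and SARD1 did pass with the Wald test and without Col-0 replicate 3 (0.645 and -0.77). APK2 also passed with the replicate number as a block and without jazQ replicate 1 (0.65).

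The 10 lists left were not called in jazQ (camera), with adjusted p from 0.0584 for light harvesting and photosystems to 0.979 for heat shock. Light harvesting was called with limma-voom, at a mean of at least 5 CPM, on TPM with the smaller pseudocount and without Col-0 replicate 1 or jazQ replicate 2, tryptophan without Col-0 replicate 2, and touch without Col-0 replicate 3. Indole glucosinolates had a median of -0.171 and a mean of -0.069 with a test direction of up, and the clock a median of -0.025 and a mean of 0.023 with a test direction of up. Of their genes EXPA11 and GASA6 fell (-0.77 ± 0.08 and -0.59 ± 0.08). GL2 (0.51 ± 0.10), FAMA (0.49 ± 0.10) and the glutathione conjugate peptidase GGP1 (AT4G30530) (0.38 ± 0.08) rose, with calls that were lost without Col-0 replicate 1 (0.55, 0.41 and 0.35) and without other single libraries. On TPM these 3 calls were lost, and that of FAMA also with only the groups compared. MYC2 (AT1G32640), the main transcription factor of the pathway, had 33.4 ± 4.23 CPM in Col-0 and 61.2 ± 21.4 in jazQ and did not pass (0.88 ± 0.25), although it passed with the Wald test and without jazQ replicate 1 (1.08) and was 0.58 without jazQ replicate 2. TSB2 (AT4G27070) (0.27 ± 0.10), LHCB3 (AT5G54270) (0.17 ± 0.06), RVE8 (AT3G09600) (0.201 ± 0.16), SOC1 (-0.16 ± 0.07), HSP18.2 (0.37 ± 0.20) and WRKY33 (-0.35 ± 0.20) did not pass either, except WRKY33 without Col-0 replicate 3 (-0.55).

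Beside JAZ10 and JAZ3, the largest rises in jazQ were in AT4G17470, an α/β-hydrolase (3.44 ± 0.28, or 4.21 without Col-0 replicate 3), AT5G35935, a transposable element gene (3.27 ± 0.16), and AT1G14250, a nucleoside phosphatase (2.496 ± 0.29). Beside JAZ1, the largest falls were in AT1G15125, a methyltransferase (-1.61 ± 0.20), the extensin EXT4 (AT1G76930) (-1.097 ± 0.10), ESE3 (AT5G25190) (-1.04 ± 0.20) and UBC11 (AT3G08690) (-1.01 ± 0.11). The call of AT1G14250 was lost with only the groups compared (2.501), and that of AT1G15125 with only the groups compared (-1.605) and without jazQ replicate 1 (-1.61). That of ESE3 was lost without Col-0 replicate 2, jazQ replicate 2 or 3, or any jazD library (-1.13, -0.97, -0.955, and -1.045 to -1.044). It was also lost without a filter (-1.05), with only the groups compared (-1.04) and on TPM without a filter (-0.99).

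The number of genes called in jazQ depended on single libraries and on the processing. With the replicate number as a block 315 genes were higher and 257 lower, the largest counts under any alternative. The count of higher genes was 90 on TPM without a filter, and that of lower genes 143 with the Wald test and 49 with only the groups compared. The count of higher genes was 104 without Col-0 replicate 1 and 93 without replicate 2, and the count of lower genes was 49, 43 and 173 without Col-0 replicates 1, 2 and 3 and 47 without jazQ replicate 2.

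The mutants shared part of their calls. Among jazQ's calls, 122 of the higher genes were also higher in jazD and 28 of the lower genes also lower. Independent lists of these sizes would share 22.2 and 10.0, and simulated unchanged groups against the same controls shared 0.05 in either direction on average. The simulated groups had on average only 0.8 and 1.1 called genes, so their overlap near 0 says little about shared controls. A further 47 genes were called in opposite directions, against 31.5 for independent lists and 0 in the simulations. The excess lay in 1 direction only, with 38 lower in jazQ and higher in jazD (10.6 for independent lists), HCHIB among them, while the 9 higher in jazQ and lower in jazD were fewer than the 20.9 of independent lists. AT1G15125 and EXT4 were also lower in jazQ and higher in jazD (3.73 ± 0.20 and 1.54 ± 0.10), and CYP79F1 (AT1G16410) of aliphatic glucosinolate synthesis and AT5G35935 were higher in jazQ and lower in jazD (0.73 ± 0.07 and -0.24 ± 0.07 for CYP79F1, and -2.64 ± 0.32 for AT5G35935 in jazD). Across genes, which are not independent replicates, the fold changes of the mutants had a correlation of 0.185 (0.506 simulated) and a covariance of 0.0397 (0.0217 simulated). The 3 controls cannot be split with 2 in each part, so part of the excess of calls in the same direction may come from the shared controls. Shared controls move both comparisons the same way, with a positive correlation in the simulations, so they would not raise the number of opposite calls. Without Col-0 replicate 1 the shared counts were 78 and 17, without replicate 2 they were 72 and 15, without replicate 3 the lower count was 69, and without jazQ replicate 2 it was 15. On TPM without a filter the higher count was 68, and with the Wald test the lower count was 47. With the replicate number as a block the shared counts were 209 and 108.

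Between the mutants, jazD had far higher transcripts of the ethylene-jasmonate branch and higher transcripts of tryptophan, indole glucosinolate and ER body genes than jazQ. PDF1.3 had 1.28 ± 0.723 CPM in jazQ and 3836 ± 306 in jazD (11.48 ± 0.64, or 12.08 without jazQ replicate 3), and HCHIB differed by 5.101 ± 0.12. GSTF10 of the indole pathway was higher in jazD (2.15 ± 0.08), while CYP79F1 of the aliphatic pathway was lower (145 ± 4.49 against 283 ± 26.8 CPM, -0.97 ± 0.07). This comparison concerns the 5 further mutations and any other difference between the lines. Of 19405 genes tested, 2918 were higher and 2678 lower in jazD than in jazQ (28.84%), with at least a 2-fold difference in 810 and 294.

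The lists called upward that held with an estimated correlation were the ERF branch (11 of 11 higher, median 5.56), ER bodies (9 of 9, 2.55), tryptophan (7 of 7, 1.501), indole glucosinolates (15 of 19, 0 lower, 1.08) and leaf senescence (8 of 9, 0 lower, 1.27), with the same counts adjusted over the list alone (camera, adjusted p from 4.19e-16 to 4.32e-06). With the estimated correlation their adjusted p in camera ran from 0.0177 to 0.0263. The median for senescence was 0.44 among genes with a mean of at least 5 CPM and 0.76 on TPM without a filter, with the call kept in both. PYK10 (2.55 ± 0.07), PAT1 (1.91 ± 0.06) and NAP (1.94 ± 0.12) were among their genes. Also higher in camera, with calls lost at an estimated correlation, were the MYC branch (9 of 10, 0 lower, median 3.22, adjusted p = 0.0789 with an estimated correlation), jasmonate synthesis (8 of 14, 0 lower, 0.51, adjusted p = 0.123) and breakdown (5 of 8, 0 lower, 1.02, adjusted p = 0.123). The same held in camera for signalling (6 of 10, 0 lower, 0.34, adjusted p = 0.0776 with an estimated correlation), sulfate assimilation (4 of 11, 0 lower, 0.57, adjusted p = 0.123) and anthocyanin (11 of 16, 0 lower, 0.501, adjusted p = 0.123). Adjusted over the list alone these had 9, 8, 5, 7, 4 and 11 higher and 0 lower. ARGAH2 (1.704 ± 0.11), LOX2 (2.82 ± 0.10), IAR3 (1.31 ± 0.10), MYC3 (AT5G46760) (0.56 ± 0.08), APR3 (1.81 ± 0.09) and LDOX (1.53 ± 0.09) had the smallest p in them. Without jazQ replicate 2, which stood apart in several JAZ genes, the median for jasmonate synthesis was 1.14.

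Lower in jazD than in jazQ in camera were aliphatic glucosinolates (16 of 18, 0 higher, median -0.55, adjusted p = 0.123 with an estimated correlation), light harvesting (20 of 40, 0 higher, -0.22, adjusted p = 0.319), the Calvin cycle (11 of 15, 0 higher, -0.32, adjusted p = 0.154), cell wall loosening (7 of 23, 0 higher, -0.695, adjusted p = 0.0665) and cell cycle (6 of 28, 0 higher, -0.14, adjusted p = 0.0665). All 5 were called at the preset correlation (camera, largest adjusted p = 0.00437) and lost with the estimated one. Adjusted over the list alone 17, 31, 13, 8 and 6 of their members were lower and 0 higher. RCA (-0.57 ± 0.07), XTH7 (-1.32 ± 0.08), the photosystem subunit PSAK (AT1G30380) (-0.35 ± 0.06) and MCM6 (AT5G44635) (-0.36 ± 0.08) fell. The other 10 lists were not called (camera, adjusted p of 0.0536 or more). Of these, touch was called on TPM, with the replicate number as a block and without jazQ replicate 2. Guard cell markers were called without a filter on counts or TPM and without jazQ replicate 1 or 3 or jazD replicate 3. Of their genes GH3.3 (1.52 ± 0.10), WRKY33 (1.29 ± 0.19), EDS5 (0.85 ± 0.17), HSP70-4 (0.69 ± 0.17) and TTG1 (AT5G24520) (0.34 ± 0.09) were higher in jazD, and GASA6 (-1.49 ± 0.08), PRR9 (-0.802 ± 0.17), SOC1 (-0.205 ± 0.07) and SPCH (AT5G53210) (-0.51 ± 0.14) were lower. The calls of TTG1, SOC1 and SPCH were lost without jazD replicate 1 (0.25, -0.22 and -0.47), and those of SOC1 and SPCH also without other single libraries. SOC1 lost its call also with the Wald test and with only the groups compared.

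Among the JAZ genes, JAZ2 and JAZ6 were lower in jazD than in jazQ (-3.54 ± 0.23 and -2.22 ± 0.18), as was JAZ3 (-0.82 ± 0.10), and JAZ10 and JAZ13 were higher (1.22 ± 0.27 and 4.15 ± 0.28, or 4.93 for JAZ13 without jazQ replicate 2). JAZ7 was lower, with 3 counts against 209 (a ratio of 70.5, 95% interval 24.1 to 341.6), and JAZ9 higher (0.86 ± 0.23). JAZ7 lost its call without jazD replicate 1 (fitted value -5.45), and its fitted value of -6.00 became -4.88 without jazQ replicate 2 and -6.87 without jazD replicate 2. JAZ9 lost its call without a filter and without jazQ replicate 1 or 3 or jazD replicate 2 or 3 (0.72, 0.79, 0.75 and 0.86). JAZ1 (-0.198 ± 0.15), JAZ5 (-1.06 ± 0.57, or -0.16 without jazQ replicate 2), JAZ8 (1.01 ± 0.67), JAZ11 (0.04 ± 0.13) and JAZ12 (0.11 ± 0.06) did not pass. JAZ8 did pass with limma-voom (1.56) and without jazQ replicate 2 (2.42). The largest other rises were in PDF1.2C (11.33 ± 0.75), PDF1.2B (AT2G26020) (11.31 ± 0.62), AT5G28810 (1 count in jazQ against 4213, a ratio of 4166 with an interval of 748 to 164560) and AT5G47260 (0 counts in jazQ, at least 206-fold higher). The largest falls were in AT5G50565 (0 counts in jazD, at least 216-fold lower), AT5G49440 (-9.73 ± 0.20), AT5G49640 (1 count against 759, a ratio of 768 with an interval of 138 to 30314), AT5G55790 (2 counts against 583, a ratio of 295 with an interval of 81.6 to 2434) and AT5G35935 (-5.91 ± 0.22). Of these, AT5G47260, AT5G50565, AT5G49440, AT5G49640 and AT5G55790 lie in the stretch of chromosome 5 described for jazD against Col-0, as do MYC3, MCM6 and SPCH. Calls came from edgeR's quasi-likelihood test. On TPM values 2231 genes were higher and 3379 lower (39.77% of calls higher, against 52.14% on counts). The counts were 2211 and 3384 with the smaller pseudocount and 2330 and 3122 without a filter. The median log2 fold change of all genes tested was -0.0587 on TPM (pseudocount 1), which was not scaled between libraries, and -0.0053 on counts.

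**Figure D3:**
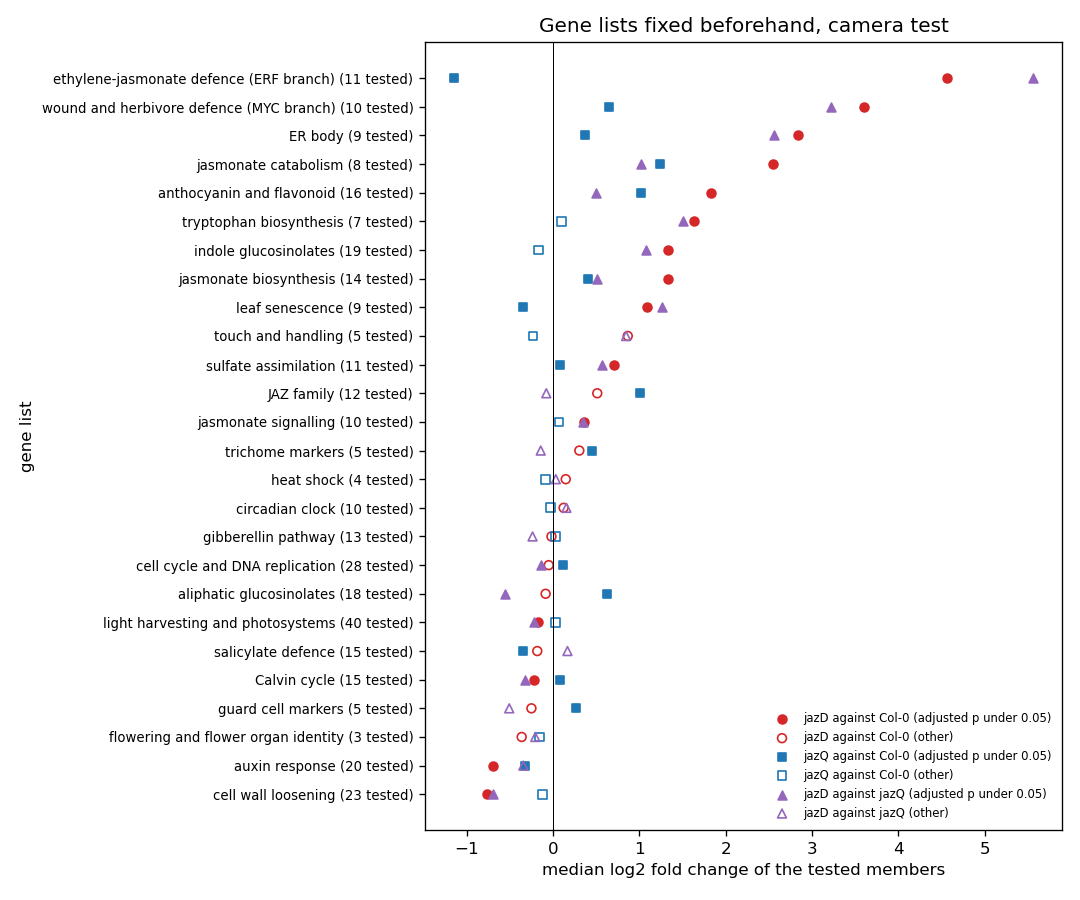
Median log2 fold change of the tested members of each gene list (horizontal axis, log2 units) for the 3 comparisons, with filled symbols where the list passed camera at adjusted p under 0.05 with the preset correlation. The ERF branch lies at 4.56 in jazD against Col-0, -1.14 in jazQ against Col-0 and 5.56 in jazD against jazQ, and cell wall loosening at -0.76, -0.12 and -0.70.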

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

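The test of scaling was chosen only after the result was seen, and the test of single libraries after the pattern had been seen but before its own result. The former replaced a first test of scaling with DESeq2 size factors, which moved almost nothing and so tested nothing. The mutants' differences from Col-0 were compared with the test of jazD against jazQ, and a result is given here where the mutants differed from Col-0 in opposite directions and that test passed. The Calvin cycle list was higher in jazQ and lower in jazD, with a median of -0.324 between the mutants, and its calls in all 3 comparisons were lost with an estimated correlation. The leaf senescence list was lower in jazQ and higher in jazD, with a median of 1.268 between the mutants (0.443 at a mean of at least 5 CPM), and its call in jazQ was lost with an estimated correlation, at a mean of at least 5 CPM and under 2 other alternatives. AT5G35935, a transposable element gene, had -5.908 between the mutants, and CYP79F1 had -0.969. AT1G15125 had 5.336, the extensin gene EXT4 2.637 and the chitinase gene HCHIB 5.101.

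The ERF branch list was lower in jazQ and higher in jazD than in Col-0, with a median of 5.559 between the mutants. Its fall in jazQ could rest on a single library. The highest median without 1 library was -0.918, without Col-0 replicate 3, so no single library decided the direction. The list's median lay at -1.138 from that of the other genes (upper quartile -0.676), and a factor per library moves all genes alike. The call in camera had already compared the list with other genes. This value restates that call and is not a separate test of scaling. Loss of the 5 JAZ genes of jazQ may lower this branch, but no library tests that apart from the line itself, and the median is the value of HCHIB, while 4 members are near-identical defensin copies.

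For chance differences, the 6 libraries of each comparison were also divided into 3 and 3 in every other way. In each comparison 1 of 10 divisions, the real one, gave as many calls as were found (5006 for jazD against Col-0, 247 for jazQ against Col-0 and 5596 for jazD against jazQ). The highest count among the other divisions was 1, 94 and 0 in these comparisons. With 10 divisions a share under 0.05 is out of reach, so this test cannot tell. The 94 came from Col-0 replicates 1 and 2 with jazQ replicate 1 against the rest.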

How the results depend on the processing

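The alternative without the chromosome 5 stretch and the lists with 4 more identifiers were chosen only after results were seen. Leaving out the stretch removed its genes from the finished calls without a new fit. No gene called in any comparison was called in the opposite direction under any alternative. Of 160 values for counts of genes, 139 kept their label, 13 were weaker and 8 stronger, and for lists 1566 of 1632 and for named genes 2900 of 3073 kept it. A count kept its label within 1.5 times the main value. A list or gene kept it with the same direction and the same side of the threshold. The tally takes in alternatives that could change little, among them DESeq2 size factors and leaving out the chromosome 5 stretch, so these shares do not measure robustness. The counts of jazD against Col-0 and of jazD against jazQ stayed within 1.5 times when 1 library was left out. The 167 genes higher in jazQ were 90 on TPM without a filter and 93 to 194 without 1 library. The 80 lower in jazQ were 143 with the Wald test, 49 with only the groups compared, and 43 to 173 without 1 library. The 122 genes higher in both mutants were 68 on TPM without a filter and 72 to 147 without 1 library, and the 28 lower in both were 47 with the Wald test and 15 to 69 without 1 library. With the replicate number as a block (replicate block), the counts in jazQ rose to 315 higher and 257 lower, the shared counts to 209 and 108, those of jazD against Col-0 to 3029 and 3026, and those of jazD against jazQ to 3405 and 3271. Libraries of the same number in different groups correlated by 0.015 to 0.306 after group means were removed, with 6 of 9 pairs over 0.1. Of 18 best matches 16 went to the same number, and 7 of 9 libraries matched best with their own number in both other groups. This is a hint from the data that the numbers mark something shared. The labels do not say what they mark and not every pair was over 0.1, so the fit without a block, chosen beforehand, was kept. Pairs under 0.1 do not show that the libraries are unpaired. The counts in jazQ and the shared counts depend on this choice. The replicate block ended the calls of the sulfate list in jazQ and of EDS5 and ALD1 in jazD against Col-0, and no other call of a list or named gene. It also added calls, for touch and handling in jazD against Col-0 and against jazQ (0.835 in both), for cell wall loosening in jazQ (-0.118), for JAZ7 in both mutants, for CYCD3;1 and TOC1 in jazD against Col-0 and for APK2 in jazQ. Directions turned only in results that had no call, and the cause was not tested. For lists the direction is that of the camera test, which can turn while the median keeps its sign. In jazD against Col-0, with 1 library left out, medians ran from -0.095 to 0.003 for aliphatic glucosinolates (-0.139 and -0.145 on TPM), -0.305 to -0.037 for salicylate defence, -0.075 to 0.076 for gibberellin and 0.058 to 0.223 for the clock. In jazQ against Col-0 they ran from -0.18 to -0.079 for indole glucosinolates, -0.024 to 0.089 for light harvesting, -0.091 to 0.158 for gibberellin (0.002 without a filter, -0.066 at 5 CPM or more, -0.018 on TPM without a filter), -0.168 to 0.011 for heat shock (-0.078 and -0.103 on TPM), -0.454 to 0.008 for touch and -0.098 to 0.137 for the clock. In jazD against jazQ the clock ran from 0.075 to 0.204, and at 5 CPM or more auxin response had 0.038 and trichome markers 0.066. JAZ11 ran from -0.078 to 0.13 in jazD against Col-0 (TPM -0.029, -0.033 and -0.029), -0.068 to 0.083 in jazQ against Col-0 (TPM -0.012, -0.014 and -0.012) and -0.088 to 0.126 in jazD against jazQ (TPM -0.017, -0.019 and -0.017), and JAZ6 from -0.263 to 0.1 in jazQ against Col-0. At these depths a gene with 0 counts in a group lies under 0.0563 to 0.0569 CPM, and in the simulations a log2 change of 0.5 was found in only 43.3 to 61.2% of genes.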

Other observations

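Gene families, the stretch of chromosome 5 and the tests of that stretch were chosen only after results were seen, while the test of genes near the JAZ loci was written before. Several gene families were called higher in jazD than in Col-0 more often than other genes. Glutathione S-transferases had 21 of 37 genes higher (adjusted p = 3.34e-08), MATE transporters 20 of 38 with 0 lower (adjusted p = 2.13e-07), and UDP-glycosyltransferases 35 of 99 (adjusted p = 3.85e-07). Each was tested with Fisher's exact test, adjusted by Benjamini-Hochberg over 38 families in both directions. Cytochrome P450 proteins (34 of 115), peroxidases (16 of 36), lectins (28 of 95), major facilitator transporters (25 of 96), 2-oxoglutarate-dependent oxygenases (20 of 69), WRKY factors (18 of 52) and chitinases (6 of 14) were also higher more often, while ABC transporters (8 of 37) did not pass. Among lower genes stood SAUR proteins (20 of 48), tubulins (8 of 12), GDSL lipases (16 of 43), kinases with leucine-rich repeats (33 of 133), methyltransferases (24 of 114), aquaporins (8 of 20), expansins (7 of 19) and pectin lyases (11 of 42). Ribosomal proteins (10 higher and 14 lower of 316) and pentatricopeptide repeat proteins (9 and 14 of 246) had fewer calls than other genes in both directions, and RING/U-box proteins (6 of 211) among lower genes. In jazQ only peroxidases passed, with 3 of 36 lower. Genes of a family are not independent replicates, and members with near-identical copies share reads.

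The genes nearly silent in jazD and expressed in Col-0 and jazQ numbered 10, and all lay on chromosome 5. The first and last of them, AT5G44490 and AT5G55790, set the ends of the stretch, so it holds all 10 by definition. Of 16 genes with the opposite pattern 1 lay in it. Nearly silent describes counts, and whether reads were present but not counted for any gene was not tested. A segment of another accession in the jazD line could explain why the 10 genes lie on 1 chromosome. Of the other 853 tested genes of the stretch 36.81% were called, against a 95th percentile of 32.12% over shifted positions. For the 3 genes with an expressed near-identical copy outside the set, reads counted for copies are an unlikely whole cause, because the level summed with copies was 31.67% of Col-0 for AT5G55790, 46.06% for AT5G51630 (the median) and 65.08% for SPL13A, while the other 7 have no such copy and were not tested. Lower depth is not a likely cause either, since the median jazD total was 103.51% of Col-0. No mutated JAZ gene lies in the stretch, its origin is unknown, and first versions of the segment and copy tests, which restated the pattern, summed SPL13A alone with its copy or took in genes without an expressed copy outside the set, were replaced after their results were seen.

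Genes close to the mutated JAZ loci could differ because segments of another accession came with the insertions. Among 50 tested genes on each side of the 10 loci, 29.67% were called between jazD and Col-0, which was at percentile 97.2 of shifted positions (median 25.54%, 95th percentile 29.21%). The share ran from 15.84% at JAZ4 to 43.0% at JAZ6. This is in line with linked segments at some loci, but clusters of coregulated genes could give the same share, and no library separates the mutations from what is linked to them.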
